A study of Neurospora crassa with 16 samples.

How the data were processed

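RNA-seq of delta epr-1 cultures was measured in 2 libraries, and 3 comparisons of wild type, delta epr-1 and delta set-7 were taken from the authors' tables. The other 14 samples, of ChIP-seq and DamID, were not analysed here. Library type was poly(A) RNA-seq, from cultures of 16 h at 32 °C. The submitters' processing notes name Bowtie2, DESeq2 and deepTools, with versions not given in the sources used here, and the genome build is not given in the sources used here.

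The per-sample table held signal in normalized counts, per the file headers and the submitters' processing notes, which the authors made with DESeq2. Each delta epr-1 column divided into whole reads for 100% of genes at a tolerance of 0.01, with size factors of 1.22 and 1.18, so reads were recovered from it. The 4 columns of wild type and delta set-7 in that table were not used here. The deposited comparison tables held log2 folds, per the file headers, with their standard errors. Whether the authors moderated (shrank) these folds is not given in the sources used here. No standard error in the 3 comparisons exceeded 0.640. For matA-2, with 0 and 1 reads in delta epr-1, it was 0.308 against wild type. Counting error alone would be larger at so few reads, which argues that the folds were shrunk. Folds and errors of genes with few reads were read as deposited, also in the steps below that use these errors. Their score was the Wald statistic of DESeq2, per the file headers. Their p-values and adjusted p-values were those the authors deposited, the latter by the Benjamini-Hochberg (BH) method. The deposited log2 folds put the first genotype over the second and were turned here so that a positive value means higher in the mutant, or higher in delta epr-1 than in delta set-7. The 3 tables came from a single fit of the same libraries.

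Genes in the tables numbered 9730, of which 9729 matched a locus tag of the NC12 annotation and 1118 had a symbol there. There were 4 summary entries beside the genes, for reads without a feature, ambiguous, unmapped or multimapping, and they held 19.1% of the reads in replicate 1 and 17.5% in replicate 2. Those entries were left out of every count of genes. The 10 highest genes held 8.97% and 9.63% of the reads in genes.

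Genes were called at an adjusted p below 0.05 with no minimum fold. Genes without an adjusted p in the deposited table were left out, which gave 8624, 8254 and 8809 tested genes for delta epr-1 against wild type, delta set-7 against wild type and the direct contrast. Named genes were the 10 with the largest fold and the 8 with a symbol and the largest fold, per direction in each mutant, the 5 with the largest fold per direction in the direct contrast, and 7 deleted, reporter or mating type genes. Gene lists and chromosome ends were tested with Fisher's exact test, neighbouring pairs with 10000 shuffles of gene order, and intervals are 95%. Fisher's exact test takes genes as independent. Members of a list and neighbouring genes may change together, so its p-values may be too small and its intervals too narrow. Intervals of read counts assume Poisson counting. The 24 gene lists gave 144 tests, adjusted together by BH, of which 22 had a BH p below 0.05. Where every member of a list was called, 0.5 was added to each cell to compare odds ratios between alternatives. Gene lists planned by words in product descriptions were replaced by families of symbols, since the reference held no descriptions, and these were fixed before any value of a member was examined. The lists cover PRC2 and EPR-1, heterochromatin, other histone methyltransferases, clock and light, conidiation, sexual development, carotenoid synthesis, amino acid synthesis, genes with no symbol, polyketide synthases and heterokaryon incompatibility. They also cover cellulose and hemicellulose degradation, other glycoside hydrolases, cell wall proteins, cytosolic ribosome, respiratory chain and ATP synthase, proteasome, chaperones, mitochondrial protein import, peroxisome biogenesis, histones, DNA repair and recombination, quinate use and vacuolar ATPase.

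To leave out a delta epr-1 library, the fold was shifted by the log2 ratio of the remaining library to the mean of both with a pseudocount of 0.5. The delta epr-1 part of the variance, solved from the 3 deposited standard errors, was doubled and BH was computed again. The remaining library was assumed to vary like the other. The same variances gave the draws with shared wild-type error. The alternatives tried were an adjusted p below 0.01, an absolute log2 fold of at least 1, a mean of at least 50 normalized counts, BH without the authors' filtering of low counts, folds recentred on their median, and either delta epr-1 library left out. Where they applied, the outermost 25 or 100 genes of each end, the removal of end genes, the removal of called genes and other pseudocounts were tried as well.

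The steps were tested on simulated data for delta epr-1 against wild type with 8254 genes. Of 100 genes simulated at a log2 fold of 1, 73% were recovered, and of 100 at 2, 97%, while 4.49% of the calls were false. Without replicate 1 these were 60%, 87% and 7.55%, and without replicate 2 they were 65%, 89% and 3.75%. The simulated errors were drawn from the deposited standard errors and tested with those same errors. The share of false calls with both libraries was thus largely set by construction. No batch was simulated, and far fewer genes changed than were called in the real comparison, so these shares do not measure real errors. The covariance found was 0.0618 where 0.0606 was put in. Of random lists 3.6% had a p below 0.05. Lists built to hold 12 called genes of 20 passed in 100% of cases. Each such list gave the same counts by construction, so this does not measure how often real lists would be found. Neighbouring pairs in random order gave 0.834 times the number under shuffling, and blocks of 4 gave 8.96 times. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.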

Results

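The series held 16 samples in 8 groups of 2 from Neurospora crassa, and asked what the loss of epr-1 does to genes kept silent under methylated lysine 27 of histone H3, beside the loss of set-7, which encodes the methyltransferase. The 2 RNA-seq libraries of delta epr-1 were analysed here, grown for 16 h at 32 °C, with replicate 1 from a mat a strain and replicate 2 from a mat A strain. Replicate 1 held 10434667 reads in genes and 9107 detected genes, and replicate 2 held 10562443 reads and 9067 detected genes. The log2 ratio of the 2 libraries had an SD of 0.33 over 8030 genes with a mean of at least 10 normalized counts, and their log2 values had a Pearson r of 0.988. Counts varied between the 2 libraries by more than counting error alone, with a chi-square of 19.1 per degree of freedom over 8128 degrees of freedom.

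The deleted gene checked the labels. NCU07505, the epr-1 gene, held 60 reads in replicate 1 (95% Poisson interval 45.8 to 77.2) and 53 in replicate 2 (39.7 to 69.3), so some reads remained at the locus in both strains. Against wild type it fell by 2.33 on the log2 scale (SE 0.24, adjusted p = 2.76e-21) in the authors' deposited table of delta epr-1, and its log2 fold was 0.07 in the authors' deposited table of delta set-7. The set-7 gene fell in delta set-7 with a log2 fold of -1.65 (SE 0.64, adjusted p = 0.0460) in the authors' deposited table, against 0.49 (adjusted p = 0.556) in the authors' deposited table of delta epr-1, or 0.32 there without replicate 1. The mating type gene matA-1 held 0 reads in replicate 1 (upper 95% limit 3.69 reads) and 62 in replicate 2, as the mating types of the strains require. These intervals cover counting error only.

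Among genes with a symbol, inv, pho-3 and cry fell most in delta epr-1, whose libraries came from a different series than the wild-type ones. The invertase gene inv had the largest fall, with a log2 fold of -5.93 (SE 0.22, adjusted p = 1.75e-161), in the authors' deposited table of delta epr-1 against wild type. The cryptochrome gene cry fell by 4.68 on the log2 scale (adjusted p = 7.2e-72), the phosphatase gene pho-3 by 4.71, the cellodextrin transporter gene cdt-1 by 3.24 and the siderophore regulator gene sre by 3.69, all by the authors' deposited table. The largest rises were those of NCU08570 (4.03), NCU09402 (3.60) and NCU10285 (3.42), and the conidiation regulator gene fl rose by 1.72 (adjusted p = 2.37e-42) in the authors' deposited table. Among genes with a symbol, cut-1 rose by 2.55, pyr-3 by 1.92 and ada-6 by 1.79 in the authors' deposited table. Each of these calls held with either library left out. Of 8624 tested genes, 2012 rose and 2110 fell at an adjusted p below 0.05, and 615 and 966 of them also changed by at least 2-fold. Since these calls rest on both libraries together, a kept sign in each library alone was nearly fixed by that choice. All 4122 kept their sign in each library alone, and 2866 of them (69.5%) were called from each library alone.

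**Figure D1:**
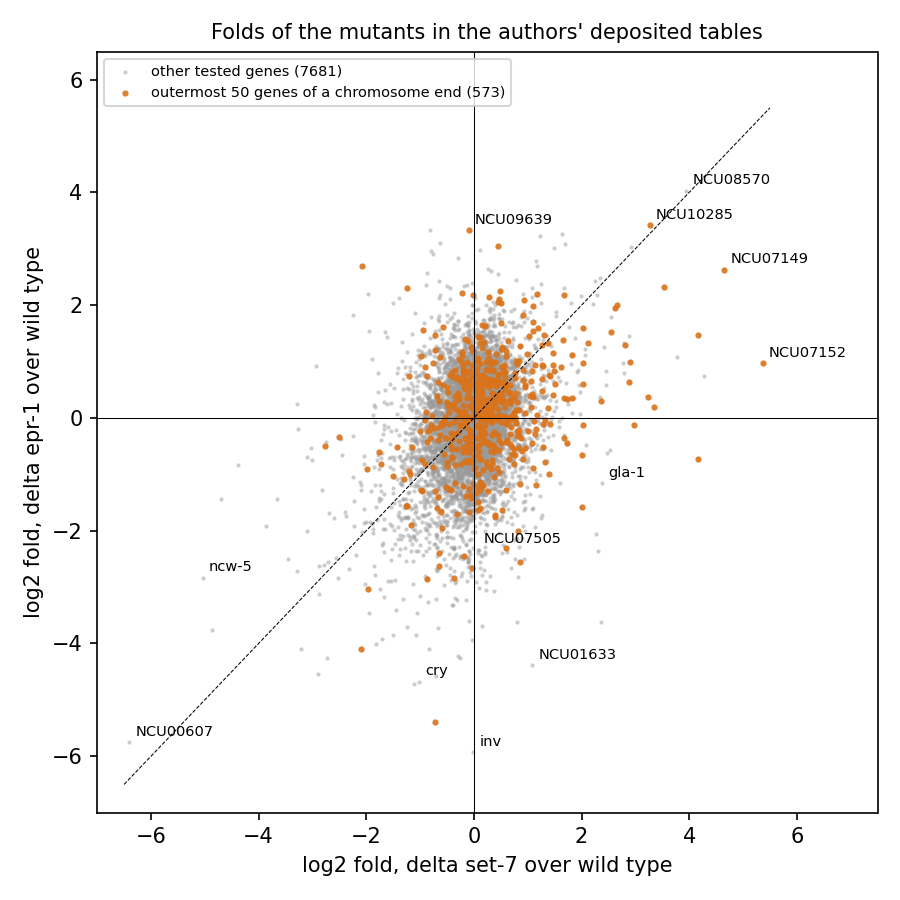
Log2 fold against wild type of delta set-7 (horizontal) and delta epr-1 (vertical), 1 point per gene, from the authors' deposited tables. Over 8142 genes the Pearson r was 0.312, and inv (-5.93 in delta epr-1, -0.02 in delta set-7) and NCU07152 (0.98 and 5.36) lay far from the diagonal.

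Respiratory chain genes and the 9 listed cytosolic ribosome genes fell in delta epr-1 as groups. The ribosome list held only genes with a symbol and does not stand for translation as a whole. Of 39 genes of the respiratory chain and ATP synthase, 33 fell and 0 rose (odds ratio of falling 17.2, 95% interval 7.21 to 41.2, Fisher BH p = 1.73e-13; 35 fell when adjusted over the list alone), with qcr7 at -1.67, cox-4 at -1.54 and nuo24 at -1.34 in the authors' deposited table. All 9 cytosolic ribosome genes fell (Fisher BH p = 4.47e-05; 9 when adjusted over the list alone), with a median log2 fold of -1.53 and crp-3 at -1.72 in the authors' deposited table. Among 23 cell wall protein genes 16 fell and 0 rose (odds ratio of falling 7.10, Fisher BH p = 8.26e-05; 16 when adjusted over the list alone), among them gel-4 (-2.83) and ncw-3 (-2.56) in the authors' deposited table. DNA repair genes went up instead, with 16 of 31 risen and 3 fallen (odds ratio of rising 3.53, Fisher BH p = 0.00745; 16 and 3 when adjusted over the list alone), among them uvs-3 (1.43), msh3 (1.35) and mus-52 (1.10) in the authors' deposited table. Without replicate 1 that odds ratio was 2.69 (Fisher BH p = 0.0881). Amino acid synthesis genes went both ways, 25 of 59 up and 14 down (odds ratio of rising 2.43, Fisher BH p = 0.00842; 26 and 14 when adjusted over the list alone), with lys-3 at 1.69 and trp-3 at -1.10 in the authors' deposited table. With a mean of at least 50 that odds ratio of rising was 2.01 (Fisher BH p = 0.0742). The amino acid synthesis genes that fell were near the share among other genes (odds ratio of falling 0.960). Medians of these lists were also set against random lists with like mean normalized counts. Respiratory chain and ATP synthase lay at percentile 0.67, ribosome at 0.99 and cell wall proteins at 2.37. DNA repair lay at percentile 99.76 and amino acid synthesis at 99.74. Genes with no symbol fell less often than the rest, 1766 of 7527 (odds ratio 0.671, Fisher BH p = 6.25e-07; 1762 when adjusted over the list alone). With only changes of at least 2-fold, the lists of respiration (odds ratio 2.39, Fisher BH p = 0.472), DNA repair (3.83, Fisher BH p = 0.0844), amino acid synthesis (1.21, Fisher BH p = 1) and genes with no symbol (0.911, Fisher BH p = 1) no longer passed.

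Lists of chromatin, light and developmental genes did not pass their tests in delta epr-1 (lowest Fisher BH p = 0.0546, for fallen histone genes), where 47.8% of all tested genes were called. In heterochromatin formation 5 of 12 genes rose and 0 fell (5 and 0 when adjusted over the list alone), with dim-9 at 0.93 and the DNA methyltransferase gene dim-2 at 0.90 in the authors' deposited table. The smallest of these rises was that of hda-4 (0.28), which was not called without replicate 1 (0.29) or without replicate 2 (0.26). Of 4 other histone methyltransferase genes 3 rose (3 when adjusted over the list alone), set-1 by 0.87 in the authors' deposited table. The other risen genes, set-2 (0.83) and dot (0.44), were not called without replicate 1 (0.78 and 0.34). Of the 3 genes for PRC2 and EPR-1, 1 rose and 1 fell (1 and 1 when adjusted over the list alone). The fall was that of the deleted gene NCU07505 itself, and cac-3 rose by 0.63, or 0.50, no longer called, without replicate 1. The planned genes eed and suz12 were not in the list. In clock and light genes, 3 of 11 rose and 5 fell (3 and 5 when adjusted over the list alone), with vvd at -2.72 and the clock gene frq at -0.79 in the authors' deposited table. In conidiation 3 of 13 rose and 5 fell (3 and 6 when adjusted over the list alone), ccg-9 by -4.10 and ccg-14 by -3.46 in the authors' deposited table. Of the risen ones, eas stood at 1.65 with both libraries but at 0.51 without replicate 1. Carotenoid synthesis had 3 of 5 genes down (3 when adjusted over the list alone), with al-2 at -1.92 in the authors' deposited table. Sexual development had 2 of 15 up and 3 down (2 and 3 when adjusted over the list alone), and histones 0 of 9 up and 6 down (0 and 6 when adjusted over the list alone), with hH1 at -0.90 in the authors' deposited table. Every delta epr-1 library came from a different series than the wild-type libraries, so batch and genotype cannot be told apart. The replicates were different strains, so the adjusted p-values of single genes measure only the spread between these samples. The Fisher p-values of lists take each gene as independent and measure no spread between samples. The deposited count of ambiguous reads also differed, by -0.87 on the log2 scale (adjusted p = 3.14e-17) in the authors' deposited table. That of unmapped reads differed by -0.84 (adjusted p = 6.26e-06).

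**Figure D2:**
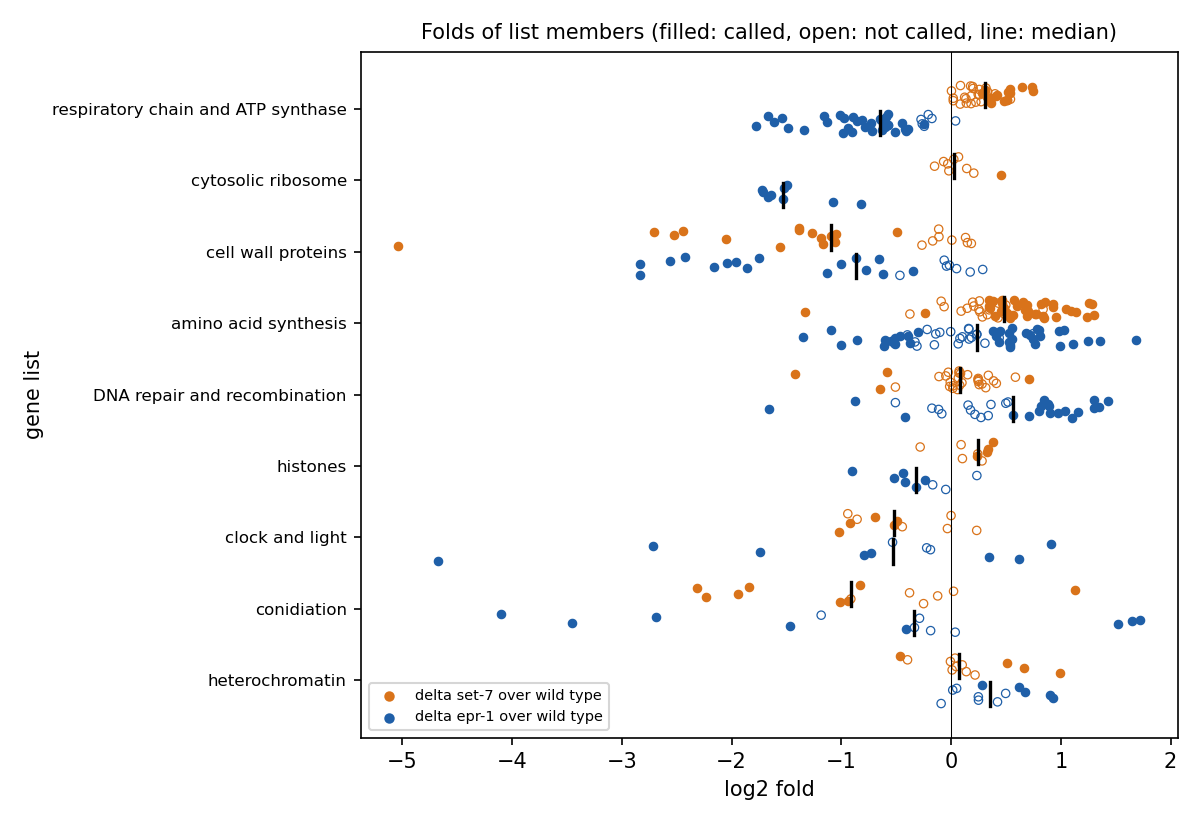
Log2 fold against wild type (horizontal) of the members of gene lists (vertical) in both mutants, from the authors' deposited tables. Respiratory chain and ATP synthase genes had a median of -0.65 in delta epr-1 and of 0.31 in delta set-7.

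In delta set-7, genes close to chromosome ends were among the largest rises, and cell wall genes were among the largest falls with a symbol. NCU07152 rose by 5.36 (SE 0.52, adjusted p = 1.17e-22) and NCU07149 by 4.66 (adjusted p = 3.84e-59) in the authors' deposited table of delta set-7 against wild type. The glucoamylase gene gla-1 rose by 2.39, nst-7 by 2.79 and set-6, the outermost gene of a chromosome end, by 1.68 in the authors' deposited table. NCU00607 fell by 6.41 on the log2 scale, and the cell wall gene ncw-5 fell by 5.04 (adjusted p = 2.05e-260), gel-4 by 2.53 and ccg-13 by 2.31 in the authors' deposited table. Of 8254 tested genes 847 rose and 956 fell, and 208 and 316 of them changed by at least 2-fold. The delta set-7 libraries were not used one by one here, so no library of this comparison could be left out.

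Biosynthesis and respiration genes rose in delta set-7, and cell wall and conidiation genes fell. Amino acid synthesis had 39 of 59 genes risen and 2 fallen (odds ratio of rising 17.8, 95% interval 10.3 to 30.7, Fisher BH p = 6.60e-23; 44 and 2 when adjusted over the list alone), with his-6 at 1.28 and thr-5 at 1.24 in the authors' deposited table. Of the respiratory chain and ATP synthase genes 17 of 39 rose and 0 fell (odds ratio 6.88, Fisher BH p = 1.37e-06; 20 when adjusted over the list alone), qcr7 by 0.74 and qcr8 by 0.65 in the authors' deposited table. Proteasome genes had 9 of 30 risen (odds ratio 3.78, Fisher BH p = 0.0170; 10 when adjusted over the list alone). Cell wall protein genes had 15 of 23 fallen and 0 risen (odds ratio 14.5, Fisher BH p = 3.91e-08; 16 when adjusted over the list alone), conidiation genes 7 of 13 fallen (odds ratio 8.96, Fisher BH p = 0.00240; 7 when adjusted over the list alone), and clock and light genes 5 of 11 fallen (odds ratio 6.39, Fisher BH p = 0.0342; 7 when adjusted over the list alone). The clock and light list no longer passed with genes called at an adjusted p below 0.01 (Fisher BH p = 0.262) with a mean of at least 50 (Fisher BH p = 0.0549) or at 2-fold (Fisher BH p = 1), and the proteasome list no longer passed with genes called below 0.01 (Fisher BH p = 0.431). At 2-fold the lists of respiration (odds ratio 0), the proteasome (0) and genes with no symbol (1.06) no longer passed either (Fisher BH p = 1 for each). In these lists ncw-3 stood at -2.71, con-10 at -2.23 and csp-1 at -0.92 in the authors' deposited table. The conidiation gene con-6 rose instead, by 1.13 (adjusted p = 0.0208), and fl, acon-2 and acon-3 were not called (0.02, -0.25 and -0.12). Genes with no symbol rose less often than the rest, 659 of 7166 (odds ratio 0.485, Fisher BH p = 7.59e-13; 652 when adjusted over the list alone). No other list named here passed (lowest Fisher BH p = 0.0546, for risen histone genes). Counts were 3 risen and 1 fallen of 12 for heterochromatin (3 and 1 when adjusted over the list alone), 0 and 4 of 13 for sexual development (0 and 4 when adjusted over the list alone), and 2 and 2 of 5 for carotenoid synthesis (2 and 2 when adjusted over the list alone). Counts were 4 and 0 of 9 for histones (5 and 0 when adjusted over the list alone) and 1 and 3 of 31 for DNA repair (1 and 3 when adjusted over the list alone). The 4 other histone methyltransferase genes gave 0 calls (0 when adjusted over the list alone), and of the PRC2 and EPR-1 genes set-7 alone fell.

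Some genes were called in both mutants. NCU08570 rose in both, by 4.03 in delta epr-1 and 3.95 in delta set-7, and NCU10285 by 3.42 and 3.27, in the authors' deposited tables. NCU00607 fell in both, with -5.76 and -6.41, and so did ncw-3 (-2.56 and -2.71), gel-4 (-2.83 and -2.53) and ncw-1 (-1.86 and -2.05), in the authors' deposited tables. Of the 8254 genes tested in both, 293 rose in both mutants and 515 fell in both. Independent lists of the same lengths would share 206 and 243 genes, but these lists were not independent. Both comparisons used the same wild-type libraries, and in draws with only their shared error, top lists of equal length had 483 risen (456 to 517) and 545 fallen genes (516 to 582) in common. Such draws gave 0.06 and 0.03 calls on average and held no effects of a single mutant, so the overlap of calls was not tested against them. The log2 folds of 8142 genes had a Pearson r of 0.312 (interval 0.284 to 0.341), where draws with only the shared wild-type error and no common response gave 0.487, and a covariance of 0.162, where those draws gave 0.0362 and at most 0.0400. Over all genes 58.6% had the same sign in both mutants against 66.2% in the draws. Genes are not independent of each other in these correlations.

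The mutants also parted. The NCU07152 gene stood 4.39 lower on the log2 scale in delta epr-1 than in delta set-7, in the authors' deposited table of the direct contrast. In that contrast inv stood at -5.91, cry at -3.65, sre at -3.84 and cdt-1 at -2.93, and fl stood at 1.70, NCU03121 at 4.14 and NCU09402 at 3.34, by the authors' deposited table. Of 39 respiratory chain and ATP synthase genes 38 were lower in delta epr-1 than in delta set-7 and 0 higher (odds ratio 124, Fisher BH p = 3.45e-21; 39 when adjusted over the list alone), and so were all 9 ribosome genes (Fisher BH p = 3.88e-05; 9 when adjusted over the list alone). Histones had 7 of 9 genes lower and 1 higher (odds ratio 11.2, Fisher BH p = 0.00824; 7 and 1 when adjusted over the list alone), and amino acid synthesis 25 of 59 lower and 9 higher (odds ratio 2.37, Fisher BH p = 0.0136; 25 and 9 when adjusted over the list alone). Among random lists with like mean normalized counts, the histone median of -0.53 lay at percentile 18.46. The lower histone genes were thus not told apart from other genes of like expression. The percentile was 0 for respiratory chain and ATP synthase, 0.24 for ribosome, 2.29 for amino acid synthesis and 99.94 for DNA repair genes. With a mean of at least 50 the odds ratio for amino acid synthesis was 1.91 (Fisher BH p = 0.104). DNA repair had 17 of 31 genes higher in delta epr-1 and 4 lower (odds ratio 4.31, Fisher BH p = 0.000791; 18 and 5 when adjusted over the list alone). The odds ratio was 2.36 without replicate 1 (Fisher BH p = 0.164) and 2.70 with genes called below 0.01 (Fisher BH p = 0.0957). Genes with no symbol were lower less often than the rest, 1741 of 7709 (odds ratio 0.610, Fisher BH p = 1.37e-10; 1734 when adjusted over the list alone). With only changes of at least 2-fold, histones (odds ratio 1.03), amino acid synthesis (1.29) and DNA repair (1.63) no longer passed (Fisher BH p = 1 for each). Over 8809 tested genes, 1948 were higher and 2097 lower in delta epr-1. This contrast too set libraries of different series against each other, and the deposited count of ambiguous reads differed by -0.68 (adjusted p = 7.53e-11) in the authors' deposited table. Unmapped reads differed by -0.41 (adjusted p = 0.0397).

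Genes near chromosome ends were found among the risen genes of both mutants more often than other genes were. The odds ratio was 2.44 in delta set-7 and 1.28 in delta epr-1, and their difference was not tested. NCU07149, NCU17053 and NCU07152, neighbours near the end of a chromosome, stood at 4.66, 3.54 and 5.36 in delta set-7 and at 2.63, 2.32 and 0.98 in delta epr-1, where NCU07152 was not called (adjusted p = 0.141, and a log2 fold of 0.43 without replicate 2), in the authors' deposited tables. NCU05173, chosen as a reporter locus like NCU07152, held 38 and 42 reads and was called in neither mutant, at 0.77 in delta set-7 and 0.13 in delta epr-1 (0.23 without replicate 1 and 0.03 without replicate 2), in the authors' deposited tables. At another end the outermost genes NCU09306, NCU09305 and NCU09304 rose by 2.81, 1.82 and 2.04 in delta set-7 in the authors' deposited table. Among the outermost 50 genes of each end, 117 of 573 (20.4%) rose in delta set-7 against 9.51% of the others (95% interval of the odds ratio 1.97 to 3.03, Fisher p = 6.22e-14). In delta epr-1, 171 of 617 (27.7%) rose against 23.0% of the others (interval 1.07 to 1.54, Fisher p = 0.00879). At an adjusted p below 0.01 that odds ratio was 1.20 (Fisher p = 0.0807). Genes that changed by at least 2-fold gave odds ratios of 6.42 in delta set-7 and 1.63 in delta epr-1. Fallen genes were scarcer at the ends, with odds ratios of 0.586 (Fisher p = 0.000685) in delta set-7 and 0.706 (Fisher p = 0.000792) in delta epr-1. In the direct contrast the odds ratio of end genes was 0.892 (Fisher p = 0.275) for genes higher in delta epr-1 and 1.18 (Fisher p = 0.0814) for genes lower, or 1.56 (Fisher p = 0.000252) for genes lower by at least 2-fold. These tests took each gene as independent, though called genes lay side by side more often than in shuffled gene order. Their p-values may thus be too small and their intervals too narrow, which matters most for the odds ratio of 1.28 in delta epr-1. Gene order came from the NC12 assembly, and the build of the deposited tables is not given in the sources used here.

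**Figure D3:**
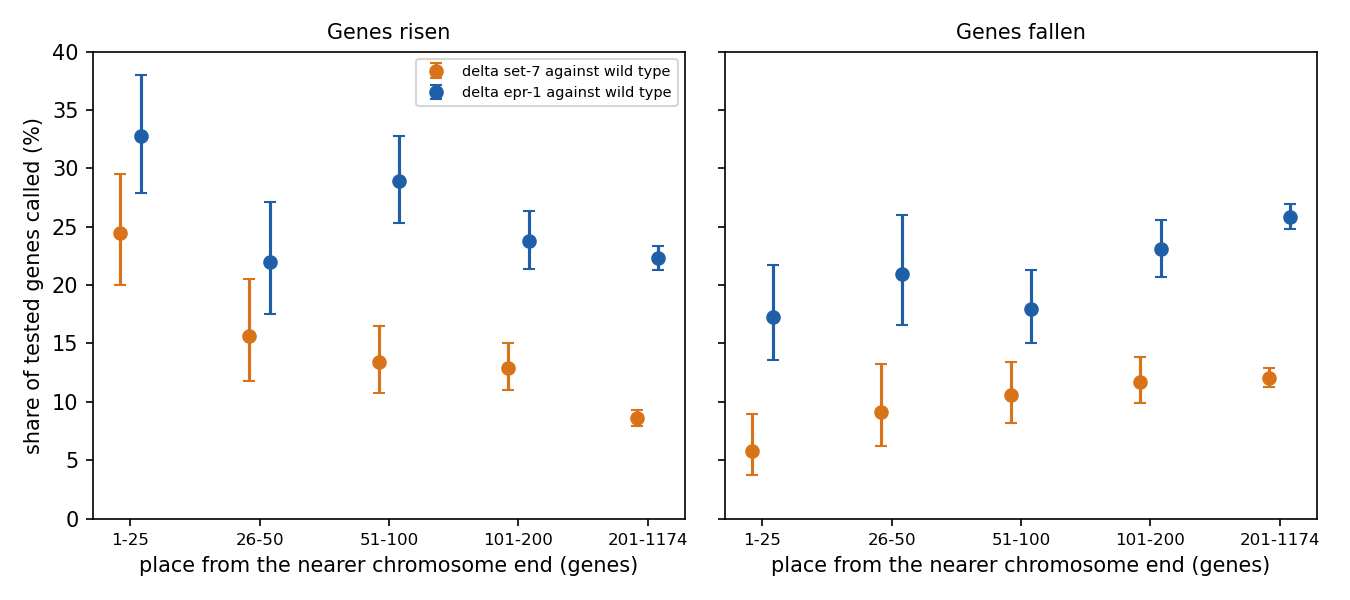
Percent of tested genes called risen or fallen (vertical) by distance in genes from the nearer chromosome end (horizontal), per mutant. In the outermost 25 genes 24.4% rose in delta set-7, falling to 8.59% in the innermost genes, beside 32.7% and 22.3% in delta epr-1. In delta epr-1 the decline was not steady, with 22.0% in genes 26 to 50 and 28.9% in genes 51 to 100.

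**Figure D4:**
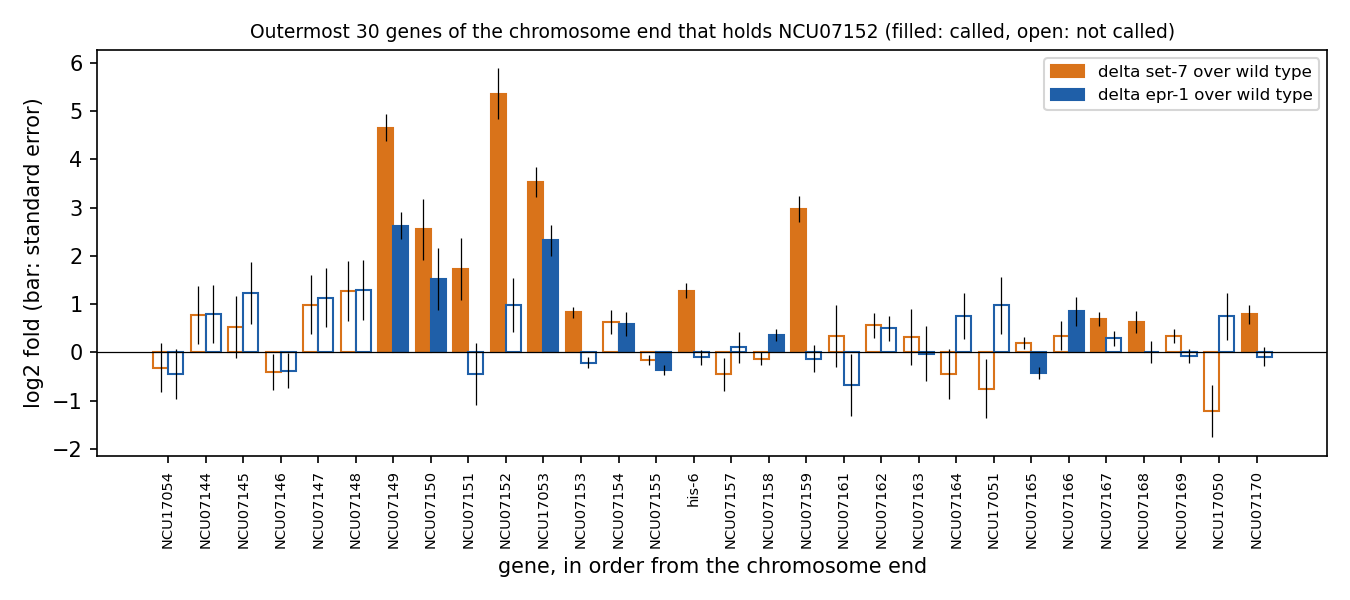
Log2 fold against wild type (vertical) of genes in order from a chromosome end (horizontal) in both mutants, from the authors' deposited tables. NCU07152 rose by 5.36 in delta set-7, and NCU07149 rose in both mutants (4.66 and 2.63).

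Genes that rose strongly in delta set-7 were chosen for that fold, which by itself favours a lower value in delta epr-1. Of 50 genes that rose at least 4-fold in delta set-7, 24 also rose in delta epr-1, 7 fell and 19 were not called, and 37 stood lower in delta epr-1 than in delta set-7. Their median log2 fold was 2.50 in delta set-7 and 0.99 in delta epr-1, and 23 of them lay among the outermost 50 genes of an end. Such genes include NCU09604, at 4.17 in delta set-7, -0.73 in delta epr-1 (-0.38 without replicate 1 and -1.20 without replicate 2) and -4.90 in the direct contrast, and NCU09633, at 4.16 and 1.48 in the mutants, in the authors' deposited tables. Called genes also lay side by side more often than in shuffled gene order, with 136 neighbouring pairs of risen genes in delta set-7 against 76.9 (permutation p = 0.0001) and 570 in delta epr-1 against 428 (permutation p = 0.0001). Fallen genes gave 206 pairs against 97.8 in delta set-7 and 667 against 470 in delta epr-1 (permutation p = 0.0001 for both, the smallest value 10000 draws can give).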

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

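The test of a library batch, and the test of genes risen in both mutants against genes risen in delta set-7 only, were chosen after the result was seen, and the other tests were set before their values were computed.

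Some genes were called in opposite directions in the mutants. The direct contrast of delta epr-1 with delta set-7 gave the size of the difference. In the authors' deposited table of that contrast NCU08441 stood at 3.74 (SE 0.22, adjusted p = 2.06e-63), NCU08856 at 4.77, NCU05767 at 4.18, NCU05788 at 4.07 and NCU07311 at 3.85. These genes rose in delta epr-1 and fell in delta set-7. The reverse held for NCU01633 at -5.47 (SE 0.15, adjusted p = 3.29e-283), NCU08739 at -5.99, gla-1 at -3.54 and arg-12 at -1.82, in the authors' deposited table of the same contrast. For arg-12 the fall in delta epr-1 was -0.51 with both libraries and -0.42, no longer called, without replicate 1. Among all genes 147 rose in delta epr-1 and fell in delta set-7, where independent lists would share 233. The reverse held for 218 genes, where independent lists would share 215. Opposite calls were thus not more frequent than in independent lists, though these lists share the wild-type libraries. Each of these genes was called in the direct contrast, which opposite calls against the same wild type make nearly certain.

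More genes were called in delta epr-1 (4122) than in delta set-7 (1803). A library batch could explain it, since delta epr-1 also differed from delta set-7 by 4045 genes while the delta set-7 libraries shared a series with the wild type. That number would also follow from the genotype, so the cause stays open. A single odd strain is unlikely to be the cause, since 3183 genes were called without replicate 1 and 3631 without replicate 2.

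End genes rose more often in both mutants. Low expression of end genes is an unlikely cause, since the odds ratio stratified by mean normalized count was 2.81 (interval 2.25 to 3.50) in delta set-7 and 1.46 (1.20 to 1.77) in delta epr-1. A state of the shared wild-type libraries might also raise them in both. Genes risen in both lay near ends more often than genes fallen in both (52 of 293 against 21 of 515, odds ratio 5.08, interval 2.99 to 8.62, Fisher p = 3.53e-10). The prediction written before would have counted this against a wild-type state, but a wild type low at its end genes gives the same asymmetry, so the question stays open.

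Over all genes the folds of the mutants had a covariance 0.126 above the mean of draws with sampling error of the shared wild-type libraries, so that error alone is an unlikely cause of it. Other measures did not exceed the draws, with r at 0.312 against 0.487 and the same sign in 58.6% of genes against 66.2%. Effects of a single mutant lower r and the share of equal signs, so these values do not bring the error back as the whole cause. Among genes called in neither mutant the covariance lay below the mean of the draws, with a difference of -0.0238. Those genes were chosen by their own calls, so that value does not decide the question. A common response or a state of the wild-type libraries beyond sampling error may explain the excess of 0.126, and these could not be told apart.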

How the results depend on the processing

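With an absolute log2 fold of at least 1, the calls were 615 up and 966 down in delta epr-1, 208 and 316 in delta set-7, and 737 and 957 in the direct contrast, as a stricter threshold must lower counts, and 8 gene list tests were called instead of 22. At an adjusted p below 0.01, 534 genes rose in delta set-7, and the odds ratio of end genes risen in delta epr-1 was 1.20 (Fisher p = 0.0807). End genes fallen in delta set-7 gave 0.659 (Fisher p = 0.141) at the 2-fold threshold. In the direct contrast, end genes higher in delta epr-1 gave 1.04 (Fisher p = 0.766) at that threshold and 0.783 (Fisher p = 0.0413) to 0.843 with a library left out, against 0.892, and end genes lower gave 1.56 (Fisher p = 0.000252) at that threshold and 1.23 (Fisher p = 0.0442) at a mean of at least 50. Without called genes r was 0.199, where draws with only the shared wild-type error gave 0.4896. The covariance was 0.0261, where those draws gave 0.04998, so the excess over all genes turned to -0.0238. These genes were chosen by their own calls, so no conclusion was drawn from this. The odds ratio of genes fallen in delta epr-1 and risen in delta set-7 changed side from 1.02 to 0.630 at the 2-fold threshold, 0.939 at a mean of at least 50 and 0.951 to 0.996 with a library left out. In delta set-7 at the 2-fold threshold, genes with no symbol gave 1.06, and respiratory chain and proteasome genes gave 0, as no member rose that far. The cause of the other changes was not tested. Of the summary values apart from single genes, 106 main ones and 136 others kept their reading. Of the main ones 10 moved, 1 reversed, 3 grew stronger and 2 weakened. Of the others 7 reversed and 23 weakened. Of named genes, list members and genes in runs, 131 values weakened without replicate 1 and 62 without replicate 2. Recentred gene lists were chosen after the data were seen. No paired analysis was possible because no pairing of libraries is given in the sources used here, and no group had enough libraries for other splits. In the delta epr-1 table genes with a mean below 1 stayed within 0.44 on the log2 scale. No standard error in the 3 comparisons exceeded 0.640, less than counting error would give at such means. This argues that the authors' treatment of folds, and not depth alone, set that limit.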

Other observations

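Further lists did not pass their tests in delta epr-1 (lowest Fisher BH p = 0.222). There 12 of 50 other glycoside hydrolases rose and 10 fell (12 and 10 when adjusted over the list alone), with gh35-1 at -2.79 and gh3-1 at -3.71 in the authors' deposited table. Cellulose and hemicellulose degradation had 3 of 25 up and 3 down (2 and 3 when adjusted over the list alone), with gh61-9 at -2.03 in the authors' deposited table. The proteasome had 9 of 30 up and 6 down (9 and 6 when adjusted over the list alone), while its regulator gene rpn-4 stood at -1.75 in the authors' deposited table. Peroxisome biogenesis had 2 of 20 up and 9 down (2 and 9 when adjusted over the list alone), with pex8 at -1.05, and the vacuolar ATPase 0 of 14 up and 4 down (0 and 4 when adjusted over the list alone), with vma-11 at -1.05, in the authors' deposited table. Chaperones had 1 of 11 up and 4 down (1 and 4 when adjusted over the list alone), and mitochondrial protein import 6 of 21 up and 6 down (6 and 7 when adjusted over the list alone). Quinate use had 0 of 7 called (0 when adjusted over the list alone), and polyketide synthases and heterokaryon incompatibility each 1 of 6 up and 1 down (1 and 1 when adjusted over the list alone).

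In delta set-7 these lists, the proteasome aside, did not pass either (lowest Fisher BH p = 0.222). The other glycoside hydrolases had 7 of 48 risen and 9 fallen (7 and 10 when adjusted over the list alone), cellulose and hemicellulose degradation 1 of 24 and 1 (1 and 1 when adjusted over the list alone), and chaperones 3 of 11 and 1 (3 and 1 when adjusted over the list alone). Vacuolar ATPase genes had 4 of 14 risen (7 when adjusted over the list alone), mitochondrial protein import 2 of 21 risen and 1 fallen (2 and 1 when adjusted over the list alone), and peroxisome biogenesis and quinate use 0 called (0 when adjusted over the list alone). Polyketide synthases had 1 of 5 fallen (1 when adjusted over the list alone) and heterokaryon incompatibility 1 of 6 (1 when adjusted over the list alone). Runs of at least 4 adjacent called genes, examined after the values were seen, numbered 5 risen and 11 fallen in delta set-7 and 34 risen and 39 fallen in delta epr-1. The longest fallen run in delta epr-1 held 9 genes, with NCU01905 at -2.29 and NCU16347 at -2.30 in the authors' deposited table. Next to inv, NCU04269 (-2.11) and NCU04268 (-1.96) fell too, and around ncw-1 the genes NCU05134 (-4.54), NCU05133 (-2.78) and NCU05132 (-2.54) fell in delta epr-1 in the authors' deposited table. NCU09187 and NCU09188, neighbours outside the outermost genes, rose in both mutants, by 2.18 and 2.16 in delta epr-1 and 2.29 and 1.98 in delta set-7, in the authors' deposited tables.

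A hypothesis is that genes near chromosome ends are held low through both set-7 and epr-1, so that genes risen in both mutants lie nearer the ends than genes risen in delta epr-1 only. Of genes risen in both 52 of 293 (17.7%) lay among the outermost 50 genes of an end, against 113 of 1569 (7.20%) of those risen in delta epr-1 and not called in delta set-7 (odds ratio 2.78, interval 1.95 to 3.97, Fisher p = 1.27e-07). The end enrichment of delta set-7 could give this without epr-1, since 47 of 336 genes risen in delta set-7 and not called in delta epr-1 lay there too. In a test chosen after that share was seen, genes risen in both lay there with an odds ratio of 1.33 (interval 0.863 to 2.04, Fisher p = 0.227) against those genes, so a part of epr-1 stays open. A low state of end genes in the shared wild-type libraries could also give these values, and the odds ratio of 5.08 for genes risen against fallen in both does not separate it. Wild-type, delta epr-1 and delta set-7 libraries made side by side, with several strains of each, would show whether end genes still rise in both mutants.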
